A study of Halocatena halophila with 21 samples.

How the data were processed

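RNA was sequenced in 21 libraries of hyphae of strain YIM 93972, a salt-loving archaeon that grows as branching hyphae and is filed under the organism name Halocatena halophila. Per the labels, the strain was grown on a nitrocellulose membrane laid over inorganic salts-starch agar at 37 °C, in dishes of 85 mm; the agar was at 2% and the salt at 25% NaCl. The wild strain was started from spores and harvested at day 14, when hyphae above the membrane (aerial) and below it (substrate) were scraped off separately. The 6 wild libraries are thus fractions of shared cultures, which the tests treat as independent samples, and the sources used here do not say which aerial and substrate libraries share plates. The 5 mutants, obtained by chemical mutagenesis, were started from broken hyphae, and their substrate hyphae were taken at day 21. Mutant and wild substrate libraries therefore differ in strain, harvest day and inoculum at once. Per the design text, 96 plates of the wild strain and 192 of each mutant were pooled into 6 biological replicates per strain, of which 3 were sequenced. Total RNA was extracted with Trizol and made into libraries with a stranded total RNA kit, per the labels' protocols.

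The authors deposited a table of expected counts, an FPKM table and an annotation table. The expected counts are estimated counts per open reading frame (ORF), deposited without scaling. Of all values, 0.591% were not whole beyond a tolerance of 1e-09, in 71 of 3752 ORFs. The deposited FPKM values were made by the authors from fragments scaled to gene length and library size. The lengths they imply correlated at 0.999 with coding length across ORFs, which are not independent, and were shorter by a median of 168 bp. The deposited annotation, per the file headers, gives other values, namely start and end on 2 chromosomes and 3 plasmids, for 3744 ORFs. It has no entry for 8 ORFs. All annotated lengths are multiples of 3, so lengths here are coding lengths. Bowtie 0.12.2 is named in the submitters' processing notes. The counting tool, its use of strand and the genome build are not given in the sources used here, so reads in stretches that ORFs share could not be told apart, and near-identical copies are uncertain. No genome sequence was used here. Every value column matched 1 sample by its name.

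Expected counts were rounded to whole numbers. The main test was edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr by group) in R 4.3.3, with all 21 libraries of the 7 groups in 1 fit so that they shared an estimate of the spread. It tested 3656 ORFs in each contrast, and a call means a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 values with standard errors computed as the size of the log2 fold change over the square root of the F statistic. Abundances are CPM scaled by TMM factors, as mean ± SD of 3 libraries. Coordinates are the deposited ones. Every adjusted p for a gene in the text is from edgeR unless another tool is named, and all tests are two-sided.

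A total of 28 gene lists were built by matching words in the product texts, with words fixed in advance of any value; 27 had at least 2 tested members. Some members match by wording alone, and they are named beside the result. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and over lists and mutants together for the mutants. An estimated correlation and fry, which tests whether a list's genes move one way and compares no list with another, were alternatives. Silent ORFs were those with at most 3 counts over a mutant's 3 libraries where the wild substrate libraries predicted at least 30, and a run was at least 3 neighbours. The analysis was tested on simulated counts, drawn around the wild substrate means with independent noise per gene and few genes changed. They held no differences in evenness between libraries and no wide shift between groups. The rates below therefore do not carry over to comparisons in which those differ. For aerial against substrate hyphae, with 3646 genes in the step, 34.3% of 2-fold, 77.6% of 4-fold and 93.9% of 8-fold changes were recovered, with 6 calls among 3426 unchanged genes. For bald_2 against wild substrate hyphae, with 3640 genes, 40% of 2-fold, 79.1% of 4-fold and 93.9% of 8-fold changes were recovered, with 13 calls among 3422 unchanged genes.

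Groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule took, for aerial against substrate hyphae, the 12 largest rises and 12 largest falls among called genes with a described product, a mean log2 CPM of at least 4 and groups that do not overlap, and the 3 largest each way without a described product. For each mutant it took 5 each way, for all mutants alike 10 each way with up to 3 hypothetical ones, and from each list up to 2 called members each way. FtsZ and DnaK were always included, as were Orc1/Cdc6 proteins called in at least 3 contrasts. The text names a part of these, picked after the values were seen. ORF_0867, ORF_1071 and ORF_1072, the aerial values of ORF_0306, ORF_0307, ORF_2467 and ORF_3683, the values of ORF_2135 and ORF_2373, and the mutant values of ORF_3672, ORF_3678 and ORF_3684 fall outside the rule and were chosen after their values were seen. The non-overlap filter was moved from unscaled to TMM-scaled CPM after the first selection had been seen, which replaced a few named genes.

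The alternatives fixed at the same time were DESeq2 1.42.0, RLE factors, no low-count filter, a 2-fold minimum, removal of the 10 most abundant genes, the replicate number as a block, limma on log2(FPKM + 1), only the compared groups in the fit, and each replicate left out in turn. Chosen after seeing the data were total counts without TMM factors, library evenness as a covariate, and the omission of 4 libraries. These were wild aerial replicate 3 (few reads) with bald_1 replicates 2 and 3 and transitional_2 replicate 3 (uneven). Evenness is the SD of log2 read density over ORFs longer than 400 bp. Total counts ranged from 405178 to 4639464 per library, with a median of 2499400. Counting intervals (95%) and the floor of 3 counts over a group cover counting error only.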

Results

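Gene expression was measured in hyphae of strain YIM 93972, a haloarchaeon whose wild form raises aerial hyphae from a substrate mycelium, by sequencing total RNA of 7 groups with 3 libraries each. The wild strain gave aerial hyphae and substrate hyphae. Substrate hyphae were also taken from 2 mutants named transitional and 3 mutants named bald, from a mutagenesis aimed at strains that differentiate poorly or not at all. Expected counts summed to between 405178 (wild aerial replicate 3) and 4639464 (transitional_1 replicate 3) per library, over 3752 ORFs. In wild aerial replicates 1, 2 and 3, 142, 141 and 389 ORFs had a count of 0, against 1 to 81 in the other 18 libraries. The closest pair of replicates, bald_2 replicates 1 and 2, still differed by more than sampling noise, with a chi-square of 2.61 per degree of freedom over genes, and no libraries were merged.

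Read density over ORFs was more uneven in aerial hyphae than in any substrate library. The SD of log2 read density over ORFs was 2.20 ± 0.0676 (SD, n = 3) in wild aerial and 0.725 ± 0.106 in wild substrate hyphae. The exact permutation test gave p = 0.1, the smallest that the 20 arrangements of these libraries allow. The 10 most abundant ORFs took 19.3%, 19.0% and 26.0% of counts in the aerial libraries and 4.48%, 4.62% and 9.18% in wild substrate libraries. Among the mutants, the SD of log2 read density was 0.515 ± 0.0228 in bald_2, 0.620 ± 0.136 in transitional_1 and 0.667 ± 0.135 in bald_3 (n = 3 each). Replicates of 1 strain differed widely in bald_1, with 0.553, 1.53 and 1.17, and in transitional_2, where replicate 3 stood at 1.30. The first principal component held 75.9% of the variance.

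**Figure D1:**
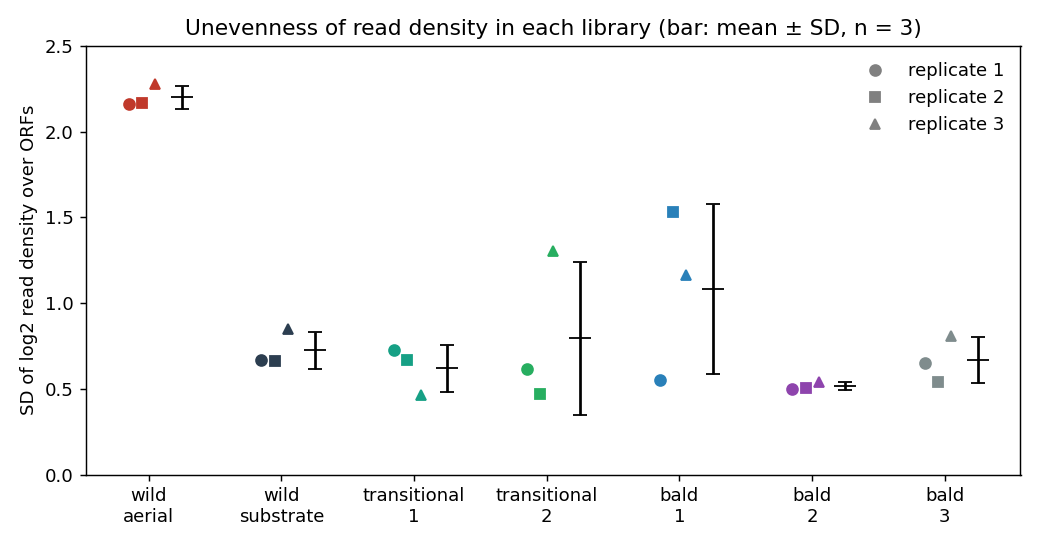
SD of log2 read density over ORFs longer than 400 bp, with 1 point per library and the mean and SD of each group (n = 3). The aerial libraries lie between 2.16 and 2.28, above all 18 substrate libraries, whose highest value is 1.53 in bald_1.

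Aerial hyphae were compared with substrate hyphae of the same strain and harvest day to find the genes that differ between the hyphal types. The PadR family transcriptional regulator ORF_0128 (chromosome 1, 123724 to 124086) rose from 252 ± 253 CPM in substrate to 4484 ± 2634 CPM in aerial hyphae (n = 3 each), a log2 fold change of +4.15 ± 0.59 (SE, adjusted p = 1.30e-05). ORF_2549, encoding FtsZ, a tubulin-like protein that forms the division ring (chromosome 1, 2413465 to 2414634), rose from 1731 ± 759 to 13042 ± 2336 CPM (+2.91 ± 1.13, adjusted p = 0.0285). The chromosomal DNA-binding protein MC1, ORF_1900, stood at 20503 ± 23306 CPM in aerial and 1822 ± 534 CPM in substrate hyphae (+3.49 ± 1.15, adjusted p = 0.0129). In the other direction, the glucuronate isomerase ORF_3335 of sugar acid breakdown (chromosome 2, 597378 to 598742) fell from 268 ± 14.6 to 2.85 ± 2.85 CPM (log2 −6.10 ± 0.49, adjusted p = 1.94e-07). The pectate lyase ORF_3367, which cleaves plant polysaccharide, fell by 5.18 ± 0.46 on the log2 scale (adjusted p = 2.72e-07). ORF_2549 was not called without wild substrate replicate 1 (adjusted p = 0.0809) or replicate 2 (0.0904), nor ORF_1900 without wild aerial replicate 3 (+2.05, adjusted p = 0.0828). ORF_0128 was at +5.43 without wild substrate replicate 3. ORF_2549 was not called with total counts (+1.72, adjusted p = 0.0874) or with FPKM in limma (+1.74, adjusted p = 0.0877), nor ORF_1900 with FPKM in limma (+1.60, adjusted p = 0.296). With library evenness as a covariate, chosen after seeing the data, ORF_2549 was at −3.90 and ORF_1900 at −2.13, and the other 3 genes kept their direction, although ORF_0128 was not called (adjusted p = 0.0519).

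Other large rises in aerial hyphae were those of the secreted-type protease ORF_0633 (peptidase S8, +3.44), the plasmid 2 transfer protein TraD ORF_3688 (+3.27), the ArsR family regulator ORF_1602 (+3.06), the iron-storage protein ferritin ORF_0684 (+3.02), the cold-shock protein ORF_0340 (+2.96), the N-acetyltransferase ORF_2760 (+2.92) and the arCOG06342 family protein ORF_1391 (+2.89). Among genes without a described product, ORF_0114 (+5.53 ± 1.47), ORF_3224 (+4.49 ± 1.22) and ORF_3660 (+4.29 ± 1.15) rose most. Large falls included 2-dehydro-3-deoxyglucarate aldolase ORF_3001 (−5.59), the BNR-repeat glycosyl hydrolase ORF_3252 (−5.88), a DNA polymerase ORF_2073 (−5.35), an amidase of cell wall peptides ORF_3356 (−5.34), a phage-type tape measure protein ORF_2044 (−5.21), a beta-lactamase family protein ORF_3098 (−5.14) and a ricin B lectin ORF_3048 (−5.12). The hypothetical ORF_2054 (−6.46 ± 0.57) and ORF_3729 (−6.78 ± 0.57) also fell. ORF_3729 and ORF_3252 had only 5 and 8 counts over the aerial libraries. By the summed counts, ORF_3729 was 111-fold lower there, with a 95% interval of 47.6 to 342 for counting error only. ORF_3252 was 58.8-fold lower, with an interval of 29.8 to 136. ORF_3068, with 3 counts over the aerial libraries, namely 1, 0 and 2, was 299-fold lower there by the summed counts, with a 95% interval of 102 to 1450 for counting error only. Its mean was 4.25 ± 6.67 CPM against 321 ± 32.5 CPM (n = 3 each), and the fitted log2 fold change was −6.96 without wild aerial replicate 2 and −9.48 without replicate 3. Without wild aerial replicate 3, ORF_0684 was at +0.81, ORF_3224 at +0.49 and ORF_3660 at +1.19, none of them called, and ORF_0633 was at +1.89, ORF_3688 at +2.34, ORF_1602 at +2.18 and ORF_0114 at +3.72, all called. Without wild substrate replicate 3, ORF_0340 was at +3.64 and ORF_0114 at +6.12. ORF_3001, ORF_3098 and ORF_3729 were at −6.39, −6.03 and −6.20 without wild aerial replicate 1, and ORF_3098 and ORF_3729 at −4.40 and −7.98 without wild aerial replicate 2. Adjusted p rose above 0.05 for ORF_0340 without wild substrate replicate 1 (0.0588) or 2 (0.0747), for ORF_1391 without those (0.0632 and 0.0819) or wild aerial replicate 1 (0.0571), and for ORF_0684 without wild substrate replicate 1 (0.0505) or 3 (0.0577). Calls of ORF_0684, ORF_0340 and ORF_1391 were also lost with total counts (+1.56, +1.85 and +1.73, with adjusted p = 0.123, 0.0633 and 0.0767) and with FPKM in limma (+0.83, +1.67 and +1.67), as were those of ORF_0114, ORF_3224 and ORF_3660 with FPKM in limma (adjusted p = 0.138, 0.406 and 0.330).

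Both FtsZ genes rose with TMM factors, the second being ORF_2479 (+1.59 ± 0.56, adjusted p = 0.0186), and neither was called with total counts or FPKM. ORF_2479 was then at +0.36 (adjusted p = 0.370) and, in limma, +0.35 (adjusted p = 0.380). Of the 14 genes for cell division and shape, 6 rose and 6 fell. Of 4 genes for the chaperone DnaK, ORF_0161 (+1.62) and ORF_0727 (+1.93) rose with TMM factors and ORF_0129 fell (−1.24). With total counts ORF_0161 and ORF_0727 were at +0.47 and +0.72 (adjusted p = 0.332 and 0.152), and with FPKM in limma at +0.34 and +0.72 (adjusted p = 0.481 and 0.126). ORF_0750 was not called with TMM factors (+0.59 ± 0.29, adjusted p = 0.0705) or total counts (−0.58, adjusted p = 0.0511). It was called higher with RLE factors (+0.72, adjusted p = 0.023), by DESeq2 (+0.73, adjusted p = 0.0087) and without wild aerial replicate 3 (+0.91, adjusted p = 0.0069), and lower with FPKM in limma (−0.69, adjusted p = 0.0222). ORF_2479 was not called without wild substrate replicate 1 (adjusted p = 0.0585) or 2 (0.0537), nor ORF_0727 without the latter (0.0572), nor ORF_0161 without wild aerial replicate 1 (0.0507) or 2 (0.0613) or wild substrate replicate 1 (0.0728) or 2 (0.0872). The Orc1/Cdc6 initiators of replication went mostly down, with 6 of 8 lower and 1 higher: Orc1 genes ORF_3534 and ORF_3559 of plasmid 1 fell (−3.83 ± 0.41 and −3.58 ± 0.39), as did ORF_3689 of plasmid 2 (−2.29 ± 0.34), while the cdc6-like ORF_1858 of chromosome 1 rose (+2.00; +0.74 and adjusted p = 0.068 with FPKM in limma). That list did not pass its test (median −1.74, camera adjusted p = 0.159). The Cdc48 gene ORF_1010, an ATPase that unfolds proteins, rose by 2.32.

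Ribosomal protein genes moved together toward aerial hyphae. Of 59 members, 56 rose and 3 fell, with a median log2 fold change of +2.44 (camera adjusted p = 3.92e-09; adjusted p = 0.637 with an estimated correlation). Examples are L4P, ORF_0962 (+3.02 ± 0.94), and L24P, ORF_0952 (+2.94 ± 0.92). Of the 3 that fell, RimK, ORF_2143 (−2.87), modifies ribosomal protein S6 and ORF_0867 (−0.73) acetylates ribosomal proteins, so neither is a ribosomal protein. The third, the S17E-like ORF_3129, had 0 aerial counts and was at least 14.6-fold lower against a floor of 3 counts over the group. Among tRNA synthetases and translation factors, 24 of 36 rose and 1 fell (median +1.06, camera adjusted p = 7.46e-05; adjusted p = 0.637 with an estimated correlation), although that median turned to −0.10 with total counts and −0.18 with FPKM. Elongation factor 1-alpha ORF_1508 rose by 2.63 and initiation factor SUI1 ORF_2689 by 2.36, and a valyl-tRNA synthetase ORF_2555 fell (−1.12). In the citric acid cycle, 11 of 17 genes rose and 1 fell (median +1.67, camera adjusted p = 0.0128; adjusted p = 0.637 with an estimated correlation). With total counts that median was +0.42, with 4 members higher and 5 lower, and with FPKM it was +0.39. The ribosomal median was then +1.28, with 24 members higher and 3 lower, and +1.23. Aconitate hydratase ORF_2702 (+2.59) and isocitrate dehydrogenase ORF_0672 (+2.46) rose, and a citrate synthase ORF_1596 fell (−1.04). Without wild aerial replicate 3 the citric acid cycle list missed the threshold (camera adjusted p = 0.0537). Calls of ORF_1508 were lost without wild aerial replicate 1 or 2 or wild substrate replicate 1 or 2 (adjusted p = 0.0555, 0.0501, 0.0856 and 0.107), those of ORF_2689 without wild aerial replicate 3 or wild substrate replicate 1 or 2 (0.0726, 0.0843 and 0.0837), those of ORF_0867 without wild aerial replicate 1 or 2 or wild substrate replicate 1 or 3 (0.238, 0.0747, 0.0756 and 0.0505), and those of ORF_2555 without any aerial replicate (0.107, 0.112 and 0.0706) or wild substrate replicate 3 (0.0982). Without wild substrate replicate 3, ORF_1508 was at +3.30 and ORF_0672 at +3.15. With total counts ORF_1508 and ORF_2689 were at +1.5 and +1.10 (adjusted p = 0.0998 and 0.166), and with FPKM in limma at +1.56 and +0.99 (adjusted p = 0.0908 and 0.275). With RLE factors ORF_2555 and ORF_0867 were not called (adjusted p = 0.0621 and 0.066), nor was ORF_2555 by DESeq2 (adjusted p = 0.0702). These 3 of 27 lists passed camera at the preset correlation, and their counts adjusted over the list alone were the same. All 10 splits of these 6 libraries into 3 and 3, the real one included, gave at least 3 lists by that test, and the highest gave 8. With library evenness as a covariate, an alternative chosen after seeing the data, the ribosomal median was −2.22, with 47 of 59 members lower and 0 higher, and that of the citric acid cycle was −1.45, with 13 of 17 lower and 0 higher.

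Genes for breaking down starch and polysaccharide leaned the other way, with 19 of 30 lower and 6 higher in aerial hyphae, but the list missed the threshold (median −1.91, camera adjusted p = 0.0531). It passed without wild aerial replicate 2 (0.0355) and without wild substrate replicate 1, 2 or 3 (0.0411, 0.0473 and 0.0449). With an estimated correlation in camera its adjusted p was 0.637. The amylase ORF_1071 (−2.75 ± 0.33) and the glucoamylase ORF_1072 (−2.31 ± 0.33), enzymes that release glucose from starch, fell, whereas the alpha-glucosidase ORF_2556 (+2.65 ± 0.50) and the chitinase ORF_2125 (+1.80 ± 0.29) rose. In this list, 4 members match by wording only, being enzymes that modify aminoglycosides. Of 23 sugar uptake genes 2 rose and 11 fell, of 35 for amino acid and peptide uptake 7 rose and 18 fell, of 18 for phosphate and iron uptake 1 rose and 10 fell, and of 31 for ion transport and osmoprotection 7 rose and 16 fell. The dipeptide-binding ORF_2669 rose (+2.79 ± 0.42) and the peptide-binding ORF_3050 fell (−4.75 ± 0.54). ORF_2556 was at +1.74 and ORF_3050 at −4.15 without wild aerial replicate 1, and ORF_2669 was at +2.08 without wild aerial replicate 3. ORF_2125 was not called with total counts (+0.65, adjusted p = 0.131) or with FPKM in limma (+0.52, adjusted p = 0.236), nor ORF_2556 with the latter (+1.10, adjusted p = 0.0662).

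Chaperone genes went up in 13 and down in 6 of 27 cases, led by the thermosome genes ORF_2639 (+2.84 ± 1.03) and ORF_2514 (+2.76 ± 0.85). ORF_2639 was not called without wild substrate replicate 1 (adjusted p = 0.0505) or 2 (0.0742), nor with total counts (+1.65, 0.0631) or FPKM in limma (+1.64, 0.0625). In the list of proteasome and secreted protease genes, 9 of 13 rose and 2 fell, with proteasome subunit alpha ORF_1841 at +2.33 and the subtilisin-like ORF_3394 at −3.66. ORF_1841 was not called with total counts (+1.09, adjusted p = 0.0647) or with FPKM in limma (+1.05, adjusted p = 0.0856). General transcription factors rose in 10 and fell in 3 of 14 cases, among them TFB genes ORF_2134 (+2.62), ORF_3683 of plasmid 2 (+2.21) and ORF_0914 (−1.84). ORF_2134 was at +3.38 and ORF_3683 at +3.05 without wild substrate replicate 3, and ORF_3683 was not called with total counts (+1.08, adjusted p = 0.0998) or FPKM in limma (+1.19, adjusted p = 0.0877). Stress and oxidative defence genes rose in 16 and fell in 6 of 33 cases, and their median of +1.17 turned to −0.03 with total counts and −0.09 with FPKM. Each of these 4 lists had a camera adjusted p of 0.11. The medians of the chaperone, protease and transcription factor lists were +1.38, +1.84 and +1.62 with TMM factors and +0.21, +0.55 and +0.38 with total counts. With total counts 2 chaperone genes were higher and 11 lower, and in each of the other 2 lists 2 were higher and 3 lower. Respiratory chain and ATP synthase genes rose in 31 and fell in 18 of 67 cases, with NADH dehydrogenase subunit J ORF_0838 at +2.85 and cytochrome d oxidase subunit II ORF_3424 at −3.62. That median was +0.66 with TMM factors, −0.53 with total counts and −0.58 with FPKM (camera adjusted p = 0.201).

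The remaining lists did not pass camera either. Higher and lower members numbered 18 and 14 of 46 for DNA replication and repair, 10 and 15 of 39 for the S-layer and glycosylation, 4 and 2 of 8 for archaella and chemotaxis, 37 and 53 of 113 for transcriptional regulators, and 2 and 3 of 12 for signal transduction. They numbered 4 and 11 of 19 for rhodopsins and carotenoids, 4 and 15 of 26 for transposases and integrases, 5 and 7 of 13 for CRISPR and restriction, and 3 and 4 of 8 for secondary metabolism. Adhesion-type proteins with PKD and similar domains had 0 higher and 3 lower of 5, type IV pili and secretion 0 and 2 of 2, and polyhydroxyalkanoate genes 1 and 0 of 2. The gas vesicle list had 0 members. Adjusted over the list alone, the counts differed in 4 lists, with 9 higher and 3 lower proteasome and protease genes, 15 higher stress genes, 32 higher respiratory genes and 1 higher sugar uptake gene. With transposase genes at 0 aerial counts set to their bound, that list's median moved from −1.97 to −1.73.

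**Figure D2:**
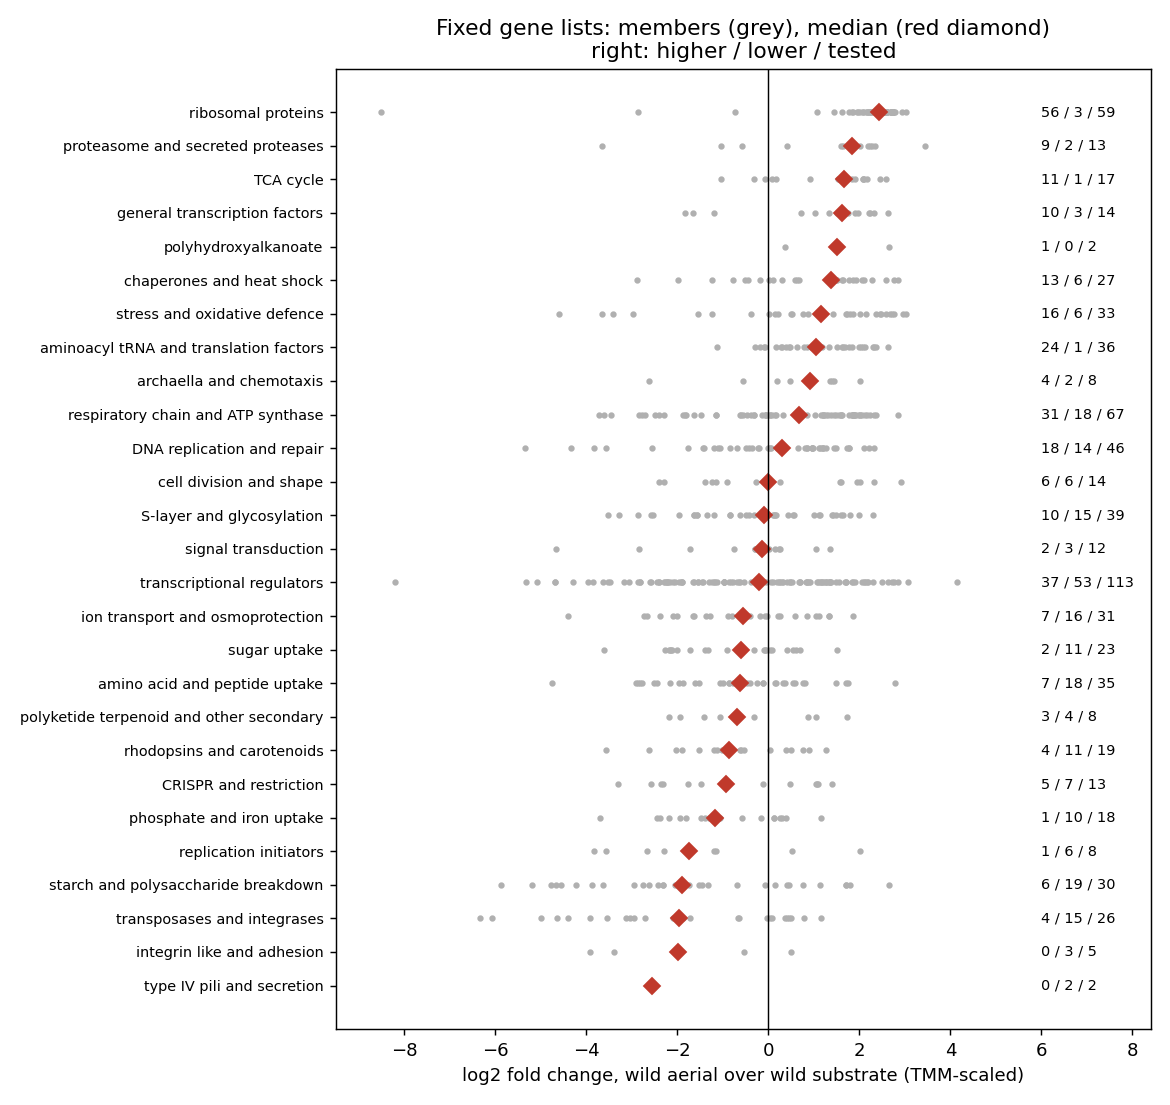
Log2 fold change of aerial against substrate hyphae for each tested member of the gene lists (edgeR, n = 3 libraries per group), with 1 point per gene and the median of each list marked. Ribosomal proteins have the highest median, +2.44 with TMM factors and +1.28 with total counts; medians between 0 and about +1.2, such as that of translation factors, fall below 0 with total counts, and ORF_3129, with 0 aerial counts, is drawn at its fitted value, which is no measure.

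Genes outside chromosome 1 were mostly lower in aerial hyphae. On chromosome 2, 496 of 697 genes fell and 52 rose, with a median log2 fold change of −1.89. The medians were −2.06 on plasmid 1 (46 of 66 fell), −1.15 on plasmid 2 (56 of 108 fell) and −3.75 on plasmid 3 (31 of 37 fell). With genes at 0 aerial counts set to their bound, the medians were −1.80 on chromosome 2 and −2.94 on plasmid 3. With total counts the medians of chromosome 2 and plasmids 1, 2 and 3 were −3.04, −3.25, −2.32 and −4.93. Chromosome 1 had 1056 of 2740 genes higher and 881 lower, with a median of +0.26 that became −0.93 with total counts and −1.09 with FPKM. Read density of chromosome 2 genes over the library median also differed between replicates of 1 mutant, and was lower in less even libraries. In replicates 1, 2 and 3 it was 0.903, 0.478 and 0.728 in bald_1 and 0.953, 1.0026 and 0.631 in transitional_2. It was 0.278 to 0.324 in aerial libraries. The fall on chromosome 2 therefore cannot be told apart from evenness.

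In all, edgeR called 2643 of 3656 genes between the hyphal types, 1130 higher and 1513 lower in aerial hyphae, of which 893 and 1265 differed at least 2-fold. The aerial and substrate ranges did not overlap for 2674 genes, where chance alone gives 10%. Genes are not independent, and every aerial library was less even than every substrate library, so that share is no yardstick for the count. The direction of many calls depends on the scaling: calls higher in aerial hyphae were 42.8% with TMM factors, with a median of −0.15 over all genes, and 7.01% with total counts (170 higher, 2254 lower), with a median of −1.35. FPKM values with limma gave 123 higher and 2422 lower. Whether the calls reflect the hyphal type or an even background of DNA reads in substrate libraries stays open. With library evenness as a covariate, which in these libraries nearly coincides with the aerial group, 113 were higher and 1222 lower, 599 of the 2643 genes were still called in the same direction, and 1455 kept their sign, called or not. Of the genes named above as higher, ORF_1900, ORF_0340, ORF_2760, ORF_1391, ORF_1858, ORF_1010, ORF_1841, ORF_2134, ORF_0838, both FtsZ genes, the thermosome genes, the DnaK genes ORF_0161 and ORF_0727, L4P, L24P, ORF_1508, ORF_2689, ORF_2702 and ORF_0672 turned lower under that covariate, and ORF_0128, ORF_3688, ORF_1602, ORF_0684, ORF_0114, ORF_3224, ORF_3660 and ORF_2669 stayed above 0 but were not called. Of those named as lower, ORF_2555 and ORF_0867 turned higher, and ORF_0129, ORF_3689, ORF_1596, ORF_3129 and ORF_1072 stayed below 0 but were not called.

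The mutants were compared with the wild strain's substrate hyphae to find what the loss of aerial growth goes with. In all 5 mutants, a pair of neighbouring hypothetical genes on chromosome 1, ORF_0306 (301104 to 301496) and ORF_0307 (301845 to 302069), was lower than in wild substrate hyphae. ORF_0306 stood at 66.5 CPM in transitional_1, 80.5 in transitional_2, 87.0 in bald_1, 48.5 in bald_2 and 50.3 in bald_3, against 1154 ± 1259 CPM in wild substrate hyphae (n = 3 each), with log2 fold changes of −4.12, −3.85, −3.73, −4.57 and −4.52. For ORF_0307 the log2 fold changes were −4.14, −3.96, −3.66, −4.67 and −5.03. The wild substrate libraries were far apart, at 534, 325 and 2603 CPM for ORF_0306 and 184, 108 and 1373 CPM for ORF_0307, while the highest mutant library had 138 and 64.2 CPM. Without wild substrate replicate 3, the log2 fold changes of ORF_0306 lay between −2.32 and −3.14, not called in transitional_2 and bald_1, and those of ORF_0307 between −1.75 and −3.10, called only in bald_2 and bald_3. Without transitional_2 replicate 3, ORF_0306 was at −4.47 in that strain. In aerial hyphae both genes rose, by 3.35 ± 0.67 and 3.35 ± 0.73 on the log2 scale, and were at +4.85 and +5.36 without wild substrate replicate 3. With library evenness as a covariate they were at +0.87 and +1.25 there, neither called (adjusted p = 0.511 and 0.457).

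The other 6 genes lower in all 5 mutants lay within 1 stretch of plasmid 2. ORF_3675, a DNA polymerase sliding clamp that holds the polymerase on DNA (54754 to 55080), stood at 297 ± 153 CPM in wild substrate hyphae and at 36.3, 39.2, 31.9, 46.5 and 37.3 CPM in transitional_1, transitional_2, bald_1, bald_2 and bald_3. Its log2 fold changes were −3.03, −2.90, −3.21, −2.67 and −2.99, with adjusted p = 0.0018, 0.0035, 0.0012, 0.0062 and 0.0025 in that order. The ArsR family regulator ORF_3680 (57678 to 58061) fell from 449 ± 168 CPM to 59.0, 64.0, 47.8, 61.0 and 59.0 CPM, with log2 fold changes of −2.93, −2.80, −3.22, −2.88 and −2.93. The other 4 encode hypothetical proteins. The log2 fold change of ORF_3676 lay between −2.43 (transitional_2) and −2.86 (bald_1), that of ORF_3678 between −1.91 (bald_3) and −2.25 (bald_1), and that of ORF_3672 between −0.92 (transitional_2, adjusted p = 0.0499) and −1.36 (bald_1). ORF_3684 lay between −3.41 (transitional_1) and −4.12 (bald_2), but its wild substrate libraries stood at 10.6, 9.56 and 47.5 CPM, against at most 4.10 CPM in a mutant library. Without wild substrate replicate 3 it was at −2.22, −2.37, −2.30, −2.93 and −2.51 in transitional_1, transitional_2, bald_1, bald_2 and bald_3 and was called in none, and without transitional_1 replicate 1 it was at −4.14 in that strain. It overlaps the end of ORF_3683 on the opposite strand (62929 to 63060 against 61991 to 62947), so reads in the short stretch they share could not be told apart.

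**Figure D3:**
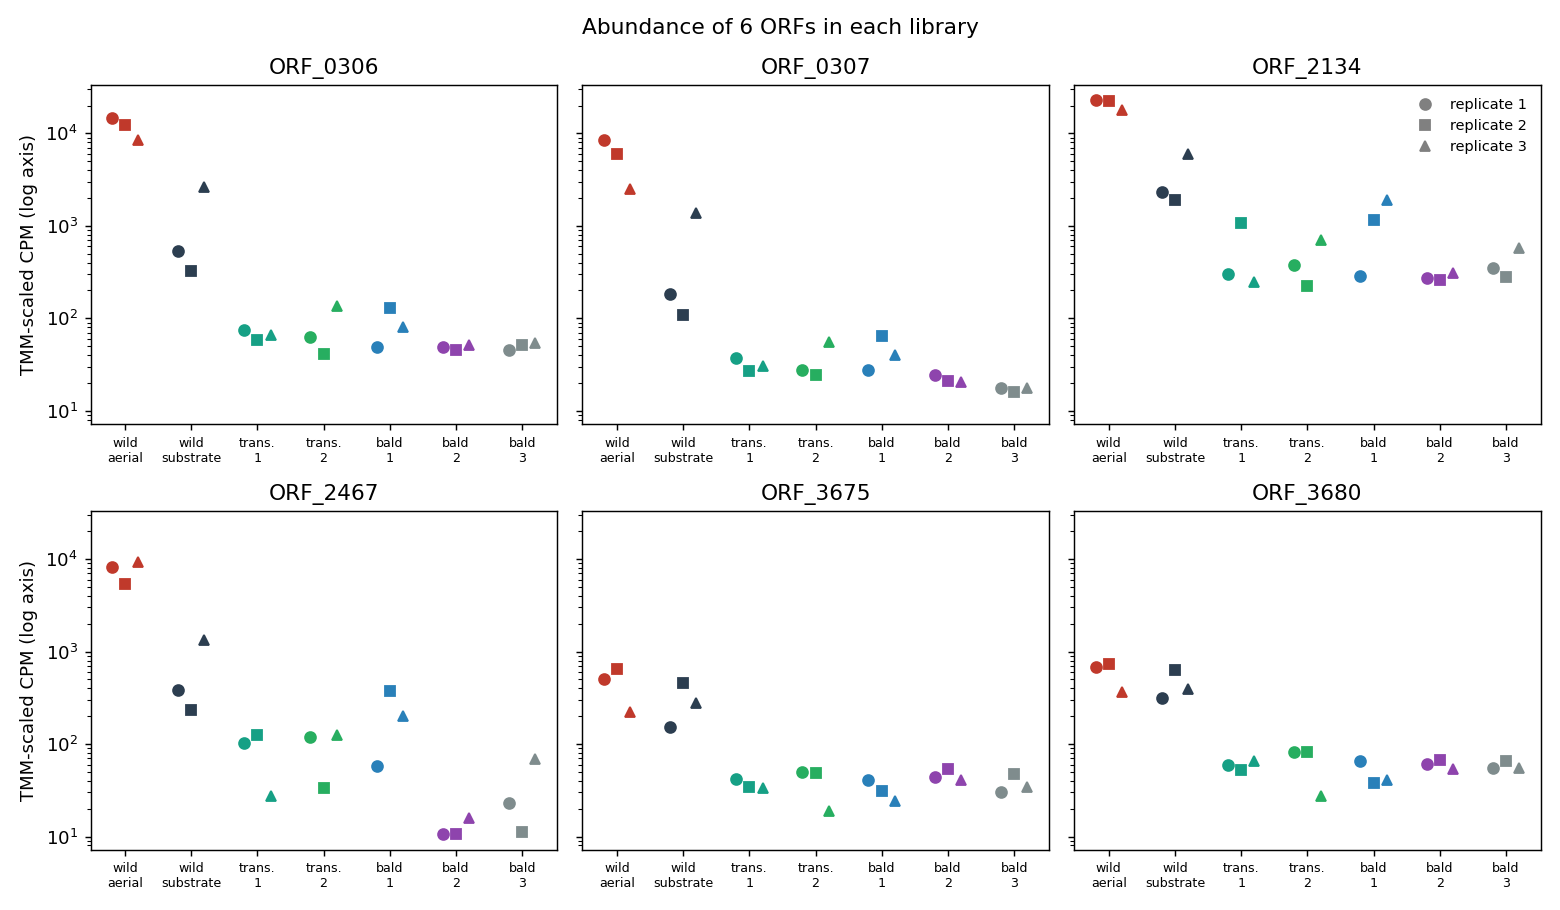
TMM-scaled CPM on a log axis of ORF_0306, ORF_0307, ORF_2134, ORF_2467, ORF_3675 and ORF_3680 by group, with 1 point per library (21 libraries) and the shape of the point giving the replicate. For ORF_0306, ORF_0307, ORF_3675 and ORF_3680 every mutant library lies below every wild substrate library.

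These 8 genes were the ones called in the same direction in all 5 mutants by edgeR, all lower and 0 higher. The mutants share the 3 wild substrate libraries as controls, which are too few to be split, so part of this overlap may come from them. In 20 simulations of unchanged mutants against those controls, the highest count was 0. Unchanged mutants hold no shift in evenness, harvest day or inoculum, so that 0 speaks only to the shared controls. Independent lists of these sizes would share 1.47e-09 genes, but lists with shared controls are not independent, so that value is no yardstick here. Leaving out 1 library changed the count to 3 without wild substrate replicate 3, to 4, 3 and 3 without transitional_1 replicates 1, 2 and 3, to 3, 3 and 4 without those of transitional_2, to 4 and 3 without bald_1 replicates 2 and 3, to 1, 2 and 1 without those of bald_2, and to 3 without any of bald_3. Over 30 comparisons of 1 mutant with wild substrate hyphae, in which each of their 6 libraries was left out in turn, ORF_3680 was called lower in 30, ORF_3676 in 28, ORF_3675 in 27, ORF_3672 in 17, ORF_0306 in 15, ORF_0307 in 13, ORF_3684 in 12 and ORF_3678 in 10. Of the 8 genes, 2 (ORF_0306 and ORF_0307) were called in all 5 mutants with total counts, 1 (ORF_0306) with FPKM in limma, 7 (all but ORF_3672) with RLE factors, 8 by DESeq2 and 0 with only the compared groups in the fit. With the replicate number as a block 5 were, all but ORF_0307, ORF_3672 and ORF_3684.

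In each mutant alone, every call was lower than in wild substrate hyphae. They numbered 14 in transitional_1, 9 in transitional_2, 21 in bald_1, 11 in bald_2 and 9 in bald_3, of which 11, 6, 17, 6 and 6 lay on plasmid 2. In bald_1, the glyoxylate cycle enzyme isocitrate lyase ORF_1664 fell from 566 ± 47.3 to 191 ± 53.3 CPM (log2 −1.57 ± 0.31, adjusted p = 0.0246), and so did its neighbour ORF_1665, a malyl-CoA lyase (−1.24 ± 0.26, adjusted p = 0.0295), and ORF_3683, the TFB of plasmid 2 (−2.72 ± 0.58, adjusted p = 0.0361). Without bald_1 replicate 2 these 3 were not called (adjusted p = 0.139, 0.122 and 0.178), nor without bald_1 replicate 3 (0.170, 0.189 and 0.0704) or wild substrate replicate 3 (0.104, 0.104 and 0.315); the log2 fold change of ORF_3683 was −3.38 and −1.96 in the last 2 fits. ORF_1664 was also lost without wild substrate replicate 2 (0.0800), and ORF_1665 without wild substrate replicate 1 (0.0594) or 2 (0.116). edgeR called none of the 3 between bald_1 and another mutant. Beside its 0 genes higher, edgeR had 114, 138, 563, 153 and 81 genes at an unadjusted p under 0.05 in either direction, and DESeq2 called 1, 2, 63, 0 and 1 genes higher and 26, 18, 47, 21 and 27 lower. Group ranges did not overlap for 671, 266, 544, 1542 and 538 genes, where chance gives 10% of 3656. Genes are not independent, so that share is no yardstick for a count. In bald_2, the fourth of these, every library was more even than every wild substrate library, which can separate many genes at once.

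The counts for single mutants hang on single libraries and on which groups share the fit. Without replicate 1, 2 or 3 of the mutant itself they were 6, 4 and 4 in transitional_1, 3, 3 and 4 in transitional_2, 865, 5 and 4 in bald_1, 1, 2 and 1 in bald_2 and 3, 4 and 3 in bald_3; the 865 in bald_1 without replicate 1, its most even library, were 395 higher and 470 lower. Without wild substrate replicate 3 they were 6 in transitional_1, 3 in transitional_2, 6 in bald_1 and 7 in bald_2, and without wild substrate replicate 2, 14 in bald_3. With only the compared groups in the fit, edgeR called 60 (8 of the 14 kept), 0, 0, 504 (11 of 11 kept) and 4 (3 of 9 kept).

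Beyond the called genes, plasmid 2 as a whole was lower in the mutants. Its 108 tested genes had median log2 fold changes of −0.97 in transitional_1, −0.64 in transitional_2, −1.13 in bald_1, −0.71 in bald_2 and −0.72 in bald_3, with 106, 100, 102, 107 and 107 of them below 0. Over all genes tested the medians lay between −0.01 (bald_1) and +0.04 (transitional_2), and the plasmid 2 medians stayed below 0 with RLE factors, total counts and FPKM. Read density of plasmid 2 genes over the library median was 2.60 ± 0.290 in wild substrate hyphae, 1.33 ± 0.0919 in transitional_1, 1.63 ± 0.769 in transitional_2, 1.24 ± 0.640 in bald_1, 1.68 ± 0.0600 in bald_2, 1.57 ± 0.135 in bald_3 and 1.69 ± 0.807 in wild aerial hyphae (n = 3 each). The wild substrate libraries lay between 2.41 and 2.93, and all 15 mutant libraries lay lower, the highest at 2.32 in transitional_2. The exact permutation test of the wild substrate against the 15 mutant libraries gave p = 0.0012, the smallest that 816 splits allow, and it treats libraries of 1 strain as separate samples.

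**Figure D4:**
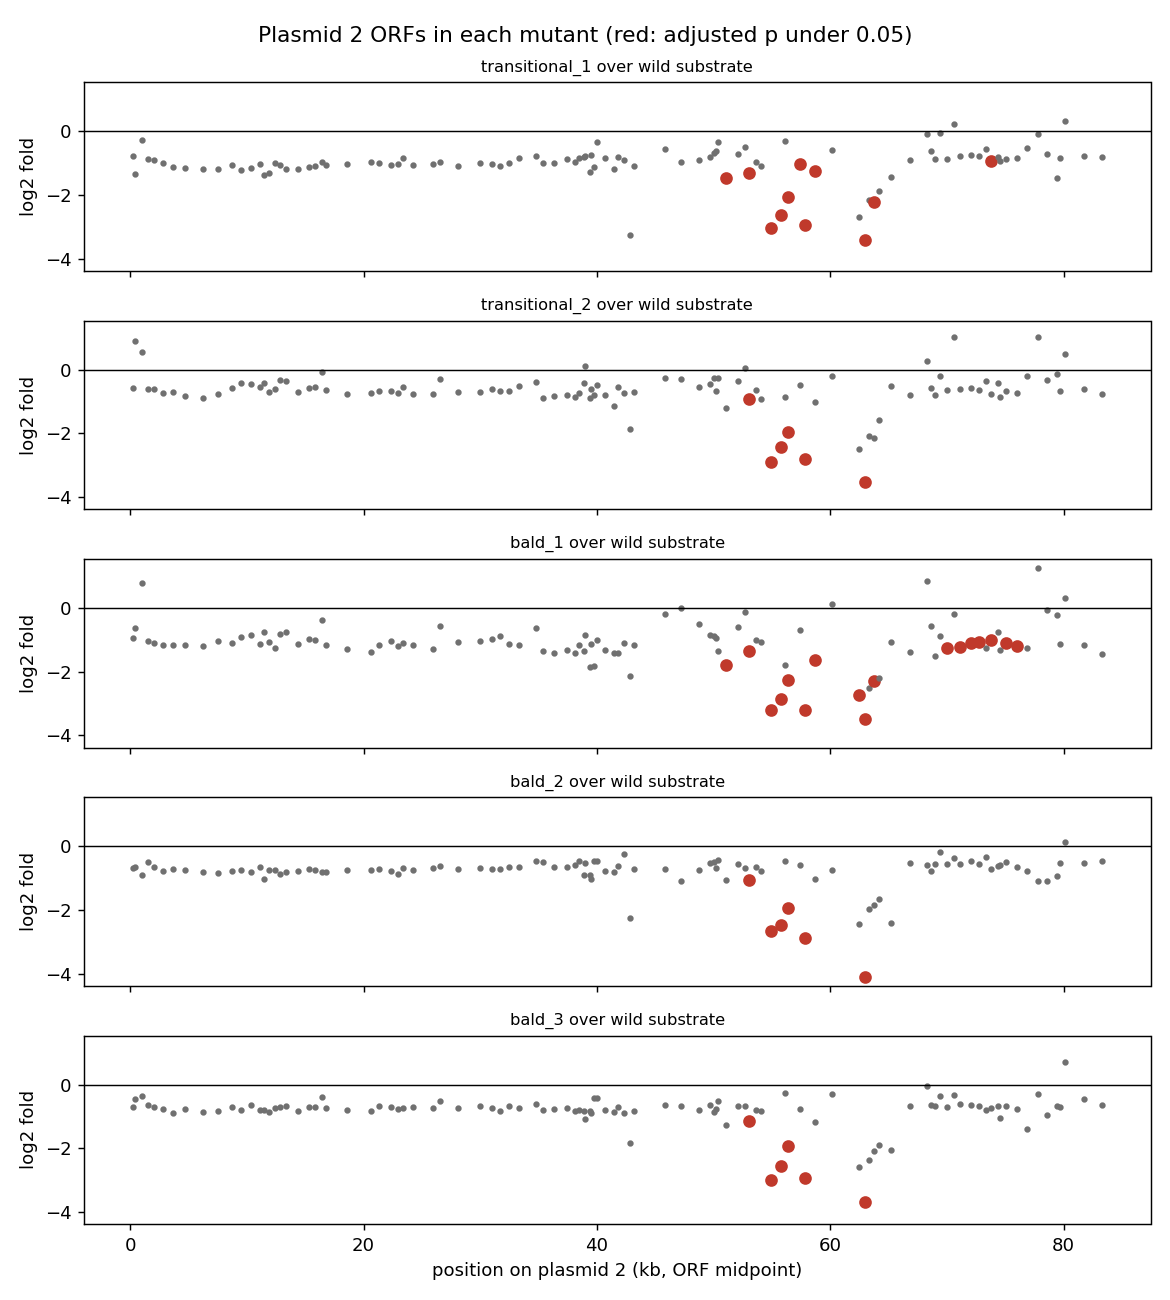
Log2 fold change over wild substrate hyphae (vertical axis, edgeR, n = 3 libraries per group) of each of the 108 tested plasmid 2 genes against its position on the plasmid in kb (horizontal axis), with 1 panel per mutant and genes at an adjusted p under 0.05 drawn as larger red points. The red points number 11 in transitional_1, 6 in transitional_2, 17 in bald_1, 6 in bald_2 and 6 in bald_3, and most other points lie below 0, around medians of −0.64 to −1.13.

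Bald and transitional mutants were compared to find genes that separate the kinds of mutant. None was called. ORF_0306 had 48.5 to 87.0 CPM in the 3 bald strains and 66.5 and 80.5 CPM in the transitional ones, and the sliding clamp gene ORF_3675 had 31.9 to 46.5 CPM against 36.3 and 39.2 CPM. edgeR called 0 genes in each of the 6 pairs of a bald and a transitional strain, against 729, 23 and 12 at an unadjusted p under 0.05 for bald_1, bald_2 and bald_3 over transitional_1 and 111, 312 and 15 over transitional_2. DESeq2 called 0 in 5 of these pairs and 33, all lower in bald_2, in bald_2 over transitional_2. With counts summed by strain, edgeR called 0 genes (48 unadjusted) and DESeq2 0, and a contrast of the means of 3 bald and 2 transitional groups gave 0 by edgeR (25 unadjusted) and 0 by DESeq2. Between bald_2 and bald_1, edgeR called 0 genes (1514 unadjusted) and DESeq2 805, of which 113 were higher in bald_2. Missing the threshold does not show that the strains are alike.

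Some gene lists passed camera in single mutants without a called member, but 98 of 100 draws of single libraries gave as many lists, with up to 41. Ribosomal protein genes had a median log2 fold change of −1.06 in bald_2 (camera adjusted p = 5.58e-11), +1.02 in bald_1 (2.89e-04), −0.27 in transitional_1 (0.0381) and −0.20 in bald_3 (0.0251). With an estimated correlation, p was 0.19, 0.397, 0.591 and 0.564 before adjustment. With total counts the medians in bald_2 and bald_1 were −0.77 and +0.48, and in bald_1 those of the citric acid cycle and of chaperones were +0.21 and +0.18. General transcription factors had medians of −0.53 in bald_2 (camera adjusted p = 0.0037), −0.31 in bald_3 (0.0025) and −0.34 in transitional_2 (0.0484), with p = 0.0167, 0.0139 and 0.0625 before adjustment with an estimated correlation. Adjusted over the list alone, 3, 3 and 2 of their 14 genes were lower. Citric acid cycle genes had medians of +0.71 in bald_1 (0.0023) and +0.21 in transitional_2 (0.0119), with p = 0.181 and 0.263 with an estimated correlation, and that of transitional_2 was +0.06 with total counts and 0.0047 with FPKM. In bald_1, chaperones (+0.67, 0.0174) and phosphate and iron uptake (−0.39, 0.0381) also passed camera, with p = 0.219 and 0.155 with an estimated correlation. So did translation factors (+0.32, 0.0307) and the respiratory chain (+0.43, 0.0043), with p = 0.397 and 0.0885 with an estimated correlation, and their medians turned to −0.10 and −0.03 with total counts. In bald_2, translation factors (−0.27, 0.0037) and starch breakdown (+0.28, 0.0484) passed, with p = 0.293 and 0.271 with an estimated correlation, and the former median was −0.0097 with total counts and −7.49e-04 with FPKM. Total counts moved the median over all genes to −0.34 in bald_1, +0.27 in bald_2 and +0.11 in transitional_1. With an estimated correlation the adjusted p was 0.977 in each of these 15 cases, and fry called 0. In bald_1 and transitional_2 the replicates of the strain also differ in the evenness of read density, as given above. In bald_2 every library was more even than every wild substrate library, with an SD of log2 read density of 0.50 to 0.54 against 0.66 to 0.85. Its list shifts cannot be told apart from that difference.

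Fold changes of aerial hyphae were set against those of bald over transitional mutants across 3656 genes, which are not independent. Pearson's r was 0.181 and Spearman's rho 0.249, with a covariance of 0.0641. The value rests on single libraries and moved with their evenness. In the fits given here, it rose when a transitional library less even than its strain's mean, or a bald one more even, was left out. The opposite omissions lowered it. It was 0.710 without transitional_2 replicate 3, 0.546 without bald_1 replicate 1, 0.434 without transitional_1 replicate 1 and 0.324 without bald_3 replicate 2. It was −0.351 without transitional_2 replicate 2, −0.220 without bald_1 replicate 2, −0.0881 without transitional_1 replicate 3, −0.0757 without transitional_2 replicate 1 and −0.0349 without bald_3 replicate 3, and 0.102 and 0.0952 without bald_1 replicate 3 and bald_2 replicate 3. Against the wild substrate libraries that both sides share, r was −0.348 for transitional_1, 0.173 for transitional_2, 0.598 for bald_1, −0.609 for bald_2 and −0.197 for bald_3, where simulated unchanged mutants gave between 0.463 and 0.472. The covariances were −0.276, 0.159, 0.847, −0.674 and −0.157, against a simulated 0.0874 to 0.0883. Across the mutants, r rose with the mean SD of log2 read density. That SD was 0.515 in bald_2, 0.620 in transitional_1, 0.667 in bald_3, 0.80 in transitional_2 and 1.08 in bald_1. Simulated unchanged mutants hold no such shift in evenness. A distance from their values therefore does not set a strain effect apart from evenness.

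No gene of the wild strain was silent in any mutant at a limit of 3 counts, with 0 silent genes in each of the 5. An even background of DNA reads in these libraries, which stays open below, could by itself keep a gene above that limit. The count therefore does not show that every gene was transcribed. The lowest ratios to the predicted count were 6.83% for ORF_0307 in transitional_1, 6.15% for ORF_0306 in transitional_2, 5.71% for ORF_0306 in bald_1, 2.32% for ORF_2467 in bald_2 and 3.42% for ORF_0307 in bald_3. Without bald_1 replicate 1, 1 hypothetical gene became silent in bald_1, ORF_2279, with 2 counts left and 36 in that replicate. In aerial hyphae, the same limits found 84 silent genes, 44 of them on chromosome 2.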

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

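The library evenness covariate, the omission of 4 libraries and the scaling by total counts were chosen only after the results were seen. Over 107 values of named genes and 12 settings, 1053 of 1236 comparisons kept direction and side of the threshold, 153 lost the call, 3 gained one and 27 reversed, and the causes were not tested. Leaving out 1 library gave 642 comparisons, of which 137 lost the call, 1 gained one and 0 reversed. The named genes are a subset picked after values were seen. Over all 193 values that the naming rule takes, 54 reversed with evenness as a covariate, 21 with FPKM, 12 with total counts, 11 without the 4 libraries and 1 each with DESeq2, RLE factors and the replicate block. Low depth limits wild aerial replicate 3 most, where 389 ORFs had 0 counts.

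Aerial against substrate calls stayed within 1.5 times of 2643 under all settings but evenness as a covariate, which left 1335. These values reversed under that covariate: ORF_1900 −2.13, ORF_0340 −3.41, ORF_0962 −2.89, ORF_0952 −2.68, ORF_2760 −1.60, ORF_2549 −3.90, ORF_1391 −3.51, ORF_2479 −2.24, ORF_0161 −2.17, ORF_0727 −2.19, ORF_0750 −0.81, ORF_1858 −0.67, ORF_1010 −1.34, ORF_2639 −3.24, ORF_2514 −2.51, ORF_1841 −2.71, ORF_1508 −3.60, ORF_2689 −3.71, ORF_2555 +0.88, ORF_2702 −2.06, ORF_0672 −1.91, ORF_0867 +0.10, ORF_2134 −0.84, ORF_0838 −1.49 and ORF_2467 −0.76. Evenness nearly coincides with the aerial group, and the cause was not tested. ORF_0750 reversed to −0.69 with FPKM and −0.58 with total counts. Leave-one-out fits gave 2188 to 2674 genes and 2 to 4 lists.

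Mutant counts, in the order transitional_1, transitional_2, bald_1, bald_2, bald_3, were 14, 9, 21, 11 and 9. They became 27, 20, 110, 21 and 28 with DESeq2, 60, 0, 0, 504 and 4 with only the compared groups in the fit, 59, 23, 44, 23 and 36 with evenness as a covariate (all calls kept), and 97, 23, 8, 85 and 49 without the 4 libraries (14, 8, 7, 11 and 9 kept), a fit in which bald_1 has 1 library, assumed to vary like the other groups. With total counts the first 4 were 3, 4, 11 and 7. With FPKM, transitional_1 had 2, bald_1 13 and bald_2 6. Leave-one-out ranges were 4 to 16, 3 to 8, 4 to 865, 1 to 14 and 3 to 14. The 8 genes lower in all 5 became 13 with DESeq2, 18 with evenness as a covariate, 2 with FPKM and 3 with total counts, and 1 to 8 over the leave-one-out fits. The causes were not tested.

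With an estimated correlation 0 lists passed for aerial hyphae and 0 for the mutants, and with fry 19 and 0. With evenness as a covariate 5 and 4 passed, and leave-one-out fits gave 11 to 21 for the mutants against 15. The correlation with bald-minus-transitional changes ran from −0.351 to 0.710 over the leave-one-out fits. Silent genes numbered 2 at a limit of 10 counts (ORF_3694 in transitional_1 and ORF_3677 in bald_1, 8 counts each) and 0 to 1 over the leave-one-out fits. For bald against transitional strains, genes that separate all strains stayed at 0 in each setting run for them, which left out fits of only the compared groups. The strain sums stayed at 0 with DESeq2, RLE factors, no low-count filter, libraries as replicates and each strain left out, and no other setting was run for them.

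With the replicate number as a block, transitional_1 had 9 genes, transitional_2 5, bald_1 12 and all mutants together 5. The deviations of same-numbered aerial and substrate libraries correlated at −0.0113, −0.175 and −0.186, so the numbers were not taken to pair the samples, although these hyphae come from shared plates. The block left 2614 genes in aerial hyphae in the fit of all libraries and 2136 in the fit of wild libraries. Named genes that lost their call in the fit of wild libraries were ORF_0684 (+1.73, adjusted p = 0.275), ORF_3224 (+1.77, 0.304), ORF_3660 (+2.32, 0.149), ORF_2555 (−1.08, 0.072) and ORF_0867 (−0.72, 0.1195).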

Other observations

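Chosen only after the results were seen were the tests of functional classes, of background DNA, of the state of single libraries, of the hyphal type, of plasmid copies, of aerial hyphae in the substrate fraction, of an even background on the chromosome and of whole strains as the reference, and the fits with evenness. The tests of depth and normalization and the other counts over splits of the samples were not.

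Functional classes from the deposited annotation (COG) were also compared, in the fit without evenness unless stated. Of 143 genes for carbohydrate transport and metabolism, 77 fell and 29 rose in aerial hyphae (median log2 −0.85; Fisher's exact test for an excess or lack of lower genes, adjusted p = 0.008), and of 109 for inorganic ion transport 57 fell and 14 rose (median −0.94, adjusted p = 0.057). A class of secondary metabolite enzymes without a sure function had 18 of 24 genes lower and 2 higher (median −1.18, adjusted p = 0.0052). The median over all genes was −0.15. With evenness in the fit it was −0.60, and these 3 classes were at −0.57, −0.43 and −0.98, so that the first 2 no longer lay below it. Translation genes had 102 of 158 higher and 21 lower (adjusted p = 2.84e-17 for higher genes), with a median of +1.18 that became 0.000653 with total counts, −0.07 with FPKM and −0.99 with evenness in the fit. Transcription genes had 58 of 119 higher and 41 lower (adjusted p = 2.53e-04), with a median of +0.82 that turned to −0.41 with total counts and −0.84 with evenness in the fit. Adjustment was over 20 classes of at least 20 genes and both directions, against 3656 genes, which are not independent.

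Wild aerial libraries differed from wild substrate libraries in most genes. Low depth of wild aerial replicate 3 cannot be the whole of it, since 2417 of the genes were still called in the same direction without that library. An even background of DNA reads in substrate libraries stays open: the 83 genes silent in aerial hyphae with a known replicon had in mutant libraries a median FPKM 1.05 times that of their replicon (0.480 to 1.27 over libraries; 0.963 to 1.11 in wild substrate hyphae), a level that such reads may give. This test was redefined after its first form, on 4 long genes, had given 0.843. Its genes needed 30 predicted counts from wild substrate hyphae, a filter that partly sets their density. Over ORFs longer than 400 bp, counts correlated with length (Spearman) at 0.72 to 0.81 in wild substrate, 0.44 to 0.89 in mutant and 0.25 to 0.31 in aerial libraries. The 5th percentile of read density was 36.5% to 47.3%, 12.4% to 57.3% and 2.05% to 2.63% of the mean, in that order. An even background would give such a contrast, but reads outside ORFs were not examined. A state of single libraries also stays open, but its test cannot decide. The difference between the least and most even replicate correlated across genes with the aerial fold change at 0.782 in transitional_2 and 0.837 in bald_1, the strains whose replicates differ most in evenness. In transitional_1, bald_3 and bald_2 the correlation was 0.639, 0.595 and 0.414. Replicates were picked by evenness, and aerial libraries are themselves less even than substrate ones, so a positive correlation is partly built in. A varying share of background reads would give one too. With evenness as a covariate 1335 calls were left. The hyphal type cannot be told apart from evenness, since every aerial library lies outside the range of the others.

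Plasmid 2 genes were lower in all mutants than in wild substrate hyphae. Normalization as the whole cause is argued against, since under the scaling nearest 0 (RLE factors or total counts) the median over the mutants was −0.67. Aerial hyphae mixed into the wild substrate fraction would not lower the 56 plasmid 2 genes that are themselves lower in aerial hyphae, yet their median over the mutants was −0.72. For the shift of the plasmid as a whole, fewer copies of plasmid 2 in the mutants, read through background DNA, is a candidate explanation that stays open. The 36 plasmid 2 genes least abundant in aerial hyphae were lower by a similar amount, with a median of −0.70. Of the genes called in all 5 mutants, ORF_3675 and ORF_3680 lay at −2.67 to −3.22 and ORF_3672 at −0.92 to −1.36. An equal drop of all plasmid 2 genes would not give such unequal falls, but these genes were picked by their calls. Strain, harvest day and inoculum differ together between wild and mutant cultures and remain untested.

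With evenness in the fit, 6 genes of chromosome 1 were lower in all 5 mutants: ORF_0306, ORF_0307, ORF_2134 (a TFB), ORF_2135, ORF_2373 and ORF_2467. They were higher in aerial than in wild substrate hyphae, by +2.36 to +3.54 on the log2 scale, in the fit without evenness, whereas with evenness in the fit they lay between −1.81 (ORF_2135) and +1.25 (ORF_0307) there, none called. A more even background in the mutant libraries would lower the other 331 chromosomal genes at least 4-fold higher in aerial hyphae (fit without evenness) as well. Their median over the mutants was −0.25 without evenness, between −1.04 and +1.0 in single mutants, and −0.27 with it, between −0.45 and −0.09. That median does not decide, because not every mutant was more even than wild substrate hyphae. The mean SD of log2 read density was 1.08 in bald_1 and 0.80 in transitional_2, against 0.725 in wild substrate hyphae. Aerial hyphae in the wild substrate fraction would put the 6 genes at equal shares of their aerial level within a library. The largest share over the smallest was 3.39, 5.19 and 2.23 in replicates 1, 2 and 3, neither equal nor far apart. All 6 shares were highest in replicate 3, at 17.7% (ORF_2467) to 39.4% (ORF_2135), against 1.91% to 11.04% in the other replicates. These values do not decide between such mixing and expression in wild substrate hyphae, and no marker of pure fractions was used here. In replicates 1, 2 and 3 the shares were 4.53%, 2.76% and 22.1% for ORF_0306, 3.25%, 1.91% and 24.2% for ORF_0307 and 11.04%, 9.10% and 28.5% for ORF_2134, against mutant means of 0.565%, 0.531% and 2.66%. Single bald_1 libraries reached the level of wild substrate replicate 2. ORF_2134 had 1927 CPM in bald_1 replicate 3 against 1905 CPM there, and ORF_2467 had 373 CPM in bald_1 replicate 2 against 233 CPM. For ORF_0306, ORF_0307, ORF_2135 and ORF_2373 every mutant library lay below every wild substrate library. Whether lower levels of these genes go with the lack of aerial growth was not tested. Pure fractions would address mixing only, since strain, harvest day and inoculum differ together between wild and mutant cultures.

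Other splits of the samples were counted for each result. Aerial against substrate hyphae gave 2643 genes and at most 34 in the other splits; each mutant gave its count against at most 0. With 10 splits each, of which 1 reached the count, a share under 0.05 is out of reach. For the 3 aerial gene lists, 10 of 10 splits gave as many, with up to 8, so their number does not set the real grouping apart. For the 8 genes lower in all mutants, 1 of 100 draws of single libraries gave as many, the real one, and the highest other gave 0. Those draws treat the libraries of 1 strain, which share harvest day and inoculum, as separate samples. With the libraries of a strain kept together, 1 of 6 strains gave as many as the reference of the other 5, the wild strain, and the highest other gave 0, and with 6 strains a share under 0.05 is out of reach. For the 15 mutant gene lists, 98 of 100 draws gave as many, with up to 41, so chance is not excluded. For the correlation of aerial with bald-minus-transitional changes, 9 of 10 ways of dividing the strains gave one at least as large in size, up to −0.773 against 0.181.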
